A study of Mus musculus with 4 samples.

How the data were processed

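RNA from 4 cultures of CD11c-enriched mouse bone marrow-derived DCs was hybridised to 1 array each, covering WT and LXR-DKO cells with GM-CSF alone or with LPS for 24 h. Per the labels, total RNA was extracted on columns and biotinylated cRNA was made with the manufacturer's amplification kit for small RNA amounts, and the strain was the same for all samples. Per the submitters' processing notes, the signals were computed with MAS5, whose version and settings are not stated. The deposited values are intensity values on a linear scale, 1 per probe set and array, with no detection calls used here. They were already scaled by the authors to a common brightness, since the mean signal after leaving out 2% of the values at each end was 200.0 on every array. The highest deposited signal was 15973.8 and the array medians lay between 25.9 and 32.9.

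The table held 45101 probe sets, of which 64 were the manufacturer's controls and were left out. Genes were named from the platform annotation, in which 34945 of the 45037 other probe sets had 1 gene symbol, 932 had several and 9160 were not listed. Probe sets with several symbols or none were not named. For 34754 probe sets the gene number matched the RefSeq gene table of the mouse assembly GRCm38.p6, which changed 0 symbols and was otherwise used only for gene neighbourhood. The main setting was fixed before the data were examined. Values were used as deposited, with a floor at the pooled median of all non-control signals, 28.9. Each gene was represented by the probe set with the highest mean signal over the 4 arrays. A gene counted as measured in a comparison when at least 1 of its arrays reached the floor, and lower values were set to the floor, so that a ratio with such a value is a lower limit on its size and is given as "at least". Genes at least 2-fold higher or lower, a log2 ratio of 1, were counted.

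Comparisons were the LPS response within each genotype, the difference of LXR-DKO over WT without and with LPS, and the difference of the log2 LPS responses, LXR-DKO minus WT. With 1 array per group no p-value was computed. The median log2 ratio of each of 28 gene lists fixed before the data were examined was set against 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays; a list is called outside when it lies beyond the central 95%. The spread between probe sets was the SD of the log2 ratio among probe sets of the same gene, pooled over genes with more than 1 probe set at or above the floor on every array involved. It covers differences within the arrays, not between cultures, mice or hybridisations.

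The genes named were set by rules fixed before the data were examined. They are Nr1h3 and Nr1h2, and the 10 genes higher and 10 lower with LPS, and likewise between genotypes, with the largest smaller-of-both log2 ratio of the same sign and all 4 values at or above the floor. They are further the 8 highest and 8 lowest for the difference of the responses, the 5 genes per direction with the largest lower limit of fold among those below the floor on both dim arrays, up to 4 members of each list with the largest ratio in the comparison described and any member needed to show that members go both ways, and Cd38 and Ccr7. Genes with only a provisional name were counted and not named. Members given in a second comparison for contrast, and those given by signal on every array, were chosen after their values were seen.

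Alternatives fixed before the data were examined were scaling to the same 75th percentile, quantile normalization, centring on the median log2 ratio of genes at or above the floor on all arrays, a floor at the 25th percentile of 8.8 or the 75th percentile of 177.4, no floor with log2 of the signal plus 16, the median ratio over all probe sets of a gene, and the use of only those probe sets without a suffix for shared targets. Scaling to the same geometric mean of hybridisation controls and leaving out genes on the X and Y chromosomes were added after seeing the data, as were 2 gene lists, NRF2 target genes and lysosomal genes.

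Counting was tested on simulated data built on the LPS response in WT over 16278 genes, with noise of 0.21 on the log2 scale per array. All 50 genes changed 4-fold and all 50 changed 8-fold were recovered as 100.0%, and 38.0% of 50 genes changed 2-fold and 10.0% of 50 changed 1.5-fold passed the threshold, against 0.044% of unchanged genes. The noise was taken from the spread between probe sets for the LPS response in WT, the smallest of the comparisons at 0.29. These shares therefore do not carry over to the genotype differences, with spreads of 0.45 and 0.54, or to variation between cultures. In a simulation over 18193 genes with independent noise for each gene, 5.0% of 200 unchanged lists lay outside the central 95% of random lists. This checks the procedure only. Members of a real list can vary together, which random lists do not reproduce, so the random range may be too narrow. Lists outside it numbered 15 of 27 for LPS in WT and 19 of 28 for LPS in LXR-DKO. There were 17 of 28 between genotypes in each condition and 12 of 28 for the difference of the responses, where 5% of 28 is 1.4. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots matplotlib 3.10.9.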

Results

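Transcript levels were measured on 4 single-channel oligonucleotide arrays of mouse dendritic cells (DCs) grown from bone marrow with the growth factor GM-CSF and enriched for the DC integrin CD11c. The cells came from wild-type (WT) mice or from mice lacking both liver X receptors, LXRα and LXRβ, which are oxysterol-activated nuclear receptors that control lipid genes (LXR-DKO). Each genotype was kept for 24 h with GM-CSF alone at 10 ng/mL, as the control, or with lipopolysaccharide (LPS), a bacterial ligand of Toll-like receptor 4, added at 100 ng/mL. This gave 4 groups with 1 array each, so no difference has a replicate check, no test across genes was made and the number of arrays limits the precision. The arrays had the same trimmed mean signal, and between 47.8% and 52.6% of their probe sets reached the floor of 28.9, the median signal. One probe set was used for each of 18193 genes, of which 12478 reached the floor on at least 1 array and 9623 on all 4. The only internal error is the spread of the log2 ratio between probe sets of the same gene, which was 0.29 for the LPS response in WT, 0.42 for the LPS response in LXR-DKO, 0.45 for the genotype difference without LPS and 0.54 with LPS.

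The targeted genes were examined first. Nr1h3, which encodes LXRα and had 1 probe set, gave signals of 108.6 in WT control, 54.5 in WT LPS, 40.4 in LXR-DKO control and 27.0 in LXR-DKO LPS. The log2 ratio of LXR-DKO over WT was -1.43 without LPS and -0.92 with LPS, the latter a lower limit on its size because the LXR-DKO LPS value lay below the floor. The position of this probe set relative to the deleted part of the gene was not known here, and a probe set outside that part checks nothing. Nr1h2, which encodes LXRβ, had no probe set with a single gene symbol in the annotation and was not analysed here, so the check covers only Nr1h3. The same held for Cd38, a surface enzyme involved in leukocyte chemotaxis, which was not analysed either.

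The first comparison asked how the cells of each genotype responded to the maturation stimulus. Genes of inflammation and of the interferon response were far higher with LPS in both genotypes. The cytokine gene Il6 had a signal of 29.3 in WT control and 2828.7 in WT LPS, a 96.5-fold difference, and of 32.7 and 5492.0 in LXR-DKO, a 168-fold difference. By the rule of the smaller of both ratios, it was followed by the neutrophil chemokine gene Cxcl1 at 27.5-fold in WT and 69.2-fold in LXR-DKO and by the cytokine gene Il1b at 27.1-fold and 36.9-fold. The acute-phase gene Saa3 was 25.2-fold and 97.0-fold higher, and the activin subunit gene Inhba 30.5-fold and 21.1-fold. Ly6i, Cfb, Rsad2, Cxcl2 and Irf7 completed the 10 highest, each at least 11.3-fold higher in both genotypes. Among genes below the floor in both control cultures, Vnn3 was at least 20.2-fold higher with LPS in WT and at least 48.5-fold in LXR-DKO. Ifit1, Il12a, Csf3 and Hamp followed, with at least 5.18-fold in WT for Hamp, whose signal with LPS was 149.7 in WT and 2479.1 in LXR-DKO.

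Of the type I interferon response list, 23 of 26 measured members were at least 2-fold higher with LPS in WT and 23 of 26 in LXR-DKO. The list's median log2 ratios of 2.65 and 2.19 both lay above all 10000 random lists matched on expression, and the latter was 1.35 with the floor at the 75th percentile. Rtp4 had log2 ratios of 4.99 in WT and 2.52 in LXR-DKO, and the 2',5'-oligoadenylate synthetase-like gene Oasl2 4.38 and at least 4.02. Of the inflammatory cytokines and mediators, 13 of 18 were at least 2-fold higher in WT and 19 of 23 in LXR-DKO, with median log2 ratios of 2.88, or 1.38 without a floor, and 2.91, or 1.81 with the floor at the 75th percentile. Il1a had log2 ratios of 5.56 and at least 6.49, and Ptgs2, the inducible cyclooxygenase, 4.73 and at least 6.26. Il18 went the other way in WT at -2.02, against -0.12 in LXR-DKO. The NF-kappaB pathway and feedback list had medians of 0.87 and 1.31, led in both genotypes by Nfkbiz at 3.32 and 2.48. The list of Toll-like receptors and adaptors had medians of 0.39 and 0.26, with Cd14 at 1.92 in WT and Tlr1 at 2.41 in LXR-DKO. Class I presentation genes had a median of 0.41 in WT, above all random lists, and of 0.12 in LXR-DKO, at the percentile of 92.8. Immediate early and heat shock genes had medians of 0.35 and 0.74, and the stress gene Ddit4 was among their highest at 1.24 and 2.10.

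Chemokine genes were higher with LPS, while receptors for chemoattractants went both ways. Among chemokines, 10 of 18 measured members in WT and 15 of 21 in LXR-DKO were at least 2-fold higher and 0 were at least 2-fold lower, with median log2 ratios of 1.31, but of 0.32 without a floor, and of 1.83. Ccl5 stood at 4.82 in WT and 2.002 in LXR-DKO, and Cxcl3 at 3.21 and 5.20. Among the receptors, S1pr3, a sphingosine 1-phosphate receptor, was higher at 1.90 and 2.56 and Ccrl2 at 1.71 and 2.11. The monocyte chemokine receptor gene Ccr2 was lower at -2.16 and -1.40 and the complement receptor gene C5ar1 at -1.47 and -2.31. Ccr7, the receptor that guides mature DCs to lymph nodes, had signals of 201.3 and 229.8 in WT without and with LPS, and of 1189.3 and 6482.5 in LXR-DKO. Its LPS ratio was thus 1.14-fold in WT and 5.45-fold in LXR-DKO. The migration signalling and adhesion list had medians of -0.15 in WT and -0.03 in LXR-DKO, the latter at the percentile of 40.5 and above 0 under median ratio scaling.

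Cell cycle genes were lower with LPS, and sterol synthesis genes had medians below 0. In WT, 29 of 32 cell cycle genes were at least 2-fold lower, with a median log2 ratio of -2.36, or of -1.34 with the floor at the 75th percentile. In LXR-DKO, 4 of 33 were, with a median of -0.62 that was still below all random lists. The mitotic cyclin gene Ccnb2 had log2 ratios of -3.15 and -0.68, Cdc20 of -3.09 and -0.74, and the chromosomal passenger gene Birc5 of -2.997 and -1.25. The cholesterol synthesis and uptake list had medians of -0.62 and -0.44, and 6 of 19 measured members were at least 2-fold lower in WT and 0 of 19 in LXR-DKO, with Dhcr7 at -1.42 and Mvk at -1.14 in WT. LXR target genes had medians of -0.49 and -0.27. Within that list the fatty acid synthase gene Fasn was lower in WT at -1.28 while Abca1, the cholesterol exporter, was higher at 4.16 in WT and 1.49 in LXR-DKO. The 10 genes lower in both genotypes by the smaller of both ratios were Ramp1, C5ar1, Mgst3, Rab3il1, Fbxo5, Ccr2, Lsm2, Tifab, Mrc1 and Asgr2. The mannose receptor gene Mrc1 was 6.81-fold lower in WT and 2.54-fold in LXR-DKO. Among genes below the floor in both LPS cultures, whose ratios are lower limits on their size, this limit reached 2-fold in both genotypes for Sgsm3 alone of the 62 found.

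In numbers, 336 genes were at least 2-fold higher and 548 lower with LPS among 11449 measured in WT, and 735 were higher and 215 lower among 11793 in LXR-DKO. Genes higher were 38.0% of those counted in WT, but 50.6% when the arrays were scaled to the same 75th percentile. Of 10764 genes measured in both genotypes, 202 were higher and 62 lower in both, where independent lists would share 18.7 and 9.27. Across the 9623 genes at or above the floor on all arrays, which are not independent replicates, the log2 responses correlated with r = 0.52.

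**Figure D1:**
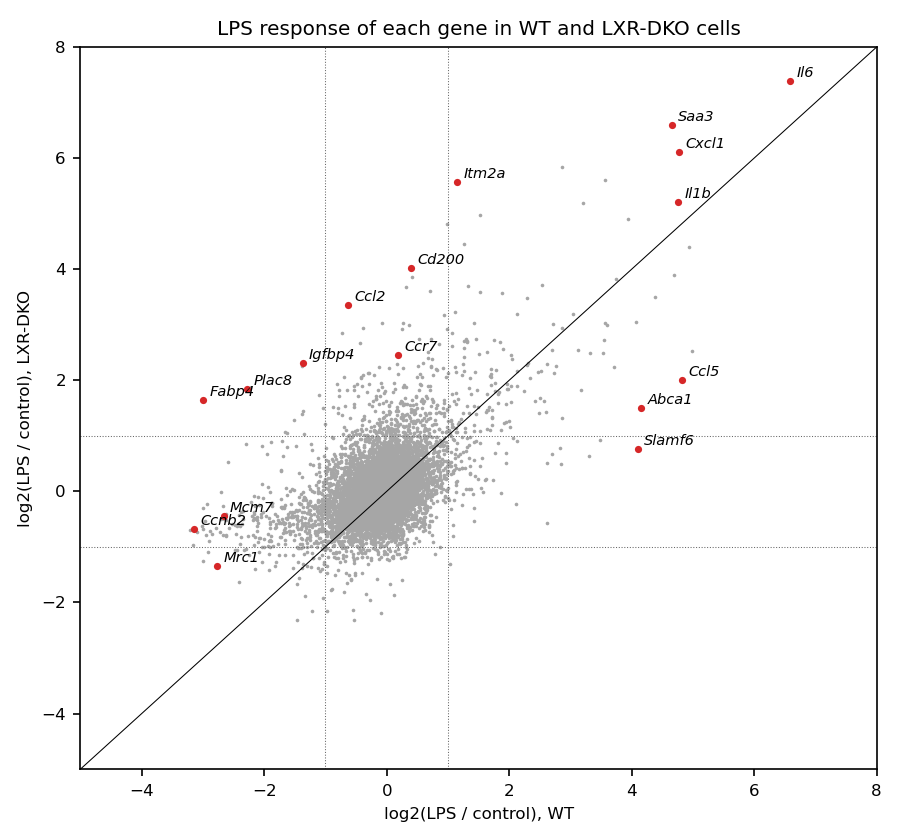
Each point is 1 gene at or above the floor on all 4 arrays, with its log2 ratio of LPS over control in WT cells on the horizontal axis and in LXR-DKO cells on the vertical axis. Dotted lines mark 2-fold and the solid line equal ratios. Il6 lies at 6.59 and 7.39, Ccr7 at 0.19 and 2.45, and Fabp4 at -3.001 and 1.65.

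The second comparison asked how cells without LXRs differed from WT cells in the absence of LPS. MHC class II presentation and conventional DC genes were higher in LXR-DKO as lists, genes of fatty acid uptake and storage were lower, and genes marking granulocytes, mast cells and B cells were higher too. Of the MHC class II presentation list, 6 of 14 members were at least 2-fold higher and 1 lower, with a median log2 ratio of 0.93. Ciita, the master regulator of MHC class II genes, had a signal of 80.6 in WT and 1239.7 in LXR-DKO, a log2 ratio of 3.94, and H2-Ob stood at 4.05 and H2-Oa at 3.49. Marchf1, a ligase that removes MHC class II from the surface, was lower at -1.01. Conventional DC markers had a median of 0.91 with 7 of 14 at least 2-fold higher and 0 lower. The integrin gene Itgae was at 4.66, the DC transcription factor genes Zbtb46 at 2.96 and Irf4 at 2.78, and Dpp4 was at least 37.6-fold higher. Beside these, neutrophil and granulocyte precursor markers had a median of 1.99, or 1.18 with only probe sets without a suffix, mast cell, basophil and eosinophil markers of 1.20, or 0.66 with the floor at the 75th percentile, and B cell markers of 1.10, but of 0.23 with the floor at the 75th percentile. The granule protein gene Ngp was at least 116-fold higher in LXR-DKO, S100a9 had a log2 ratio of 5.75, Siglecf of 2.61 and the B cell gene Ms4a1 of at least 2.85. Not all members took part: the granulocyte collagenase gene Mmp8 was lower at -1.04 and the B cell gene Cd22 at -0.73.

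The lipid lists had medians of opposite sign, and members of each list went both ways. The PPAR gamma and lipid storage list had a median of -0.79, with 6 of 14 members at least 2-fold lower, among them the fatty acid carrier gene Fabp4 at -3.92, Angptl4 at -3.05 and the scavenger receptor gene Cd36 at -2.25. Aldh1a2, which makes retinoic acid, was higher at 4.39. LXR target genes had a median of 0.59 in LXR-DKO over WT, or 0.24 at the lowest of the alternatives, and 8 of 19 were at least 2-fold higher. Those were led by the phospholipid transfer protein gene Pltp at 4.18, Abca1 at 3.20, Apoe at least at 3.03 and the desaturase gene Scd1 at 2.82, and Smpdl3a was lower at -1.11. The 6 members below 0 also included Abcg1 at -0.62, Lpl at -0.60 and the targeted gene Nr1h3, itself in this list, at -1.43. Cholesterol synthesis and uptake genes had a median of 0.62.

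Receptors for chemoattractants again went both ways, with 6 of 16 at least 2-fold higher and 2 lower in LXR-DKO and a median of -0.01, above 0 under hybridisation control scaling and with the median over probe sets. Higher were Gpr183, which guides cells along oxysterols, at 2.73, Ccr7 at 2.56, the leukotriene receptor gene Cysltr1 at 1.91 and Ccr2 at 1.52, and lower was C3ar1 at -1.25. Of the chemokines, 6 of 19 were at least 2-fold higher and 7 lower. Ccl24 was higher by at least 4.47 and Ccl5 by 3.12 on the log2 scale, while Ccl2 stood at -4.06 and Ccl3 at -3.81. The migration signalling and adhesion list had a median of 0.17, but of -0.02 under scaling to the same 75th percentile, with Mmp9 at 3.36 and the integrin gene Itgb7 at 3.14 against Trem2 at -3.91 and Bst1 at -2.39. DC maturation genes had a median of 0.63, with the chemokine gene Ccl22 at 2.95 and the costimulatory ligand gene Icosl at 2.68 against Cd200 at -2.78. Inflammatory cytokines and mediators had a median of -1.003, but of -0.24 without a floor, with Acod1, which makes itaconate, at -4.03 and the neutrophil gene Lcn2 at 5.78 or more. Immediate early and heat shock genes had a median of -0.48, with the AP-1 gene Fos at -4.58. Cell cycle genes had a median of 0.68, and 9 of 33 members were at least 2-fold higher and 0 lower. Macrophage and monocyte markers had a median of 0.36, or 0.025 at the lowest of the alternatives, and did not move together. The complement genes C1qa, C1qb and C1qc had signals of 5335.4, 6280.6 and 5386.1 in LXR-DKO and of at most 108.4 in WT control, while the lysosomal glycoprotein gene Cd68 was lower at -1.31.

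With LPS, the medians of the DC maturation and cell cycle lists, above 0 already without LPS, were higher. That of the inflammatory cytokines and mediators had the opposite sign, but covered 23 measured members instead of the 16 without LPS. Of the DC maturation list, 16 of 21 members were at least 2-fold higher in LXR-DKO and 0 lower, with a median log2 ratio of 2.05, or of 1.35 with the floor at the 75th percentile. Ccr7 was 28.2-fold higher, and the actin-bundling gene Fscn1, with signals of 640.6 and 9182.7, stood at 3.84. Of the cell cycle genes, 30 of 32 were at least 2-fold higher, with a median of 2.27, or of 1.16 with the same higher floor, and with Ccnb2 at 3.57 and the replication helicase gene Mcm7 at 3.40. Inflammatory cytokines and mediators had a median of 0.61, and 8 of 23 members were at least 2-fold higher and 6 lower. MHC class II presentation genes had a median of 1.52 and conventional DC markers of 1.89, in which Itgae was at least at 6.02. Neutrophil markers had a median of 2.25, mast cell, basophil and eosinophil markers of 2.40, or 1.25 with that floor, and B cell markers of 2.26, or 1.13 after quantile normalization. The mast cell and basophil protease genes Cpa3 and Mcpt8 were at 4.01 and at least 3.92, and Ms4a1 at least at 4.88. The type I interferon response list was lower in LXR-DKO, with a median of -0.97 and 12 of 26 members at least 2-fold lower, including Oasl2 at -1.98 and Gbp2 at -1.72. Mx1 was higher at 4.61, and so was Xaf1 by its brightest probe set, although its other probe set went the opposite way. Chemokines had a median of 0.43, but of 0.034 at the lowest of the alternatives, and lay outside the random range under 6 of 9 alternatives. Members went both ways, with the DC chemokine gene Ccl22 at 2.44 and Ccl17 at 1.54 against Ccl4 at -1.25. Receptors for chemoattractants had a median of 0.11, below 0 after quantile normalization, under 75th percentile scaling, with the floor at the 75th percentile and without a floor, with Gpr183 at 3.67 and Ccr2 at 2.27 against C3ar1 at -1.62. The migration signalling and adhesion list had a median of 0.48, or 0.18 at the lowest of the alternatives, and 15 of 34 members were at least 2-fold higher and 5 lower. LXR target genes had a median of 0.73, and the PPAR gamma and lipid storage list of -0.62, with Cd36 at -2.90 and the lysosomal lipase gene Lipa at -1.89. Cholesterol synthesis and uptake genes had a median of 0.78, with Stard4 at 1.85 and Idi1 at 1.66.

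The 10 genes highest in LXR-DKO in both conditions, by the smaller of both ratios, were Asgr2, Klk1b11, Asb2, Ifitm6, Il2ra, Ctse, Pltp, Ighm, Aif1 and Ltb. Asgr2, an asialoglycoprotein receptor gene, was 43.4-fold higher without LPS and 60.8-fold with LPS, and Il2ra, the interleukin 2 receptor alpha chain, 46.0-fold and 23.2-fold. Ighm had 8 probe sets reaching the floor, and these did not all go the same way. The 10 lowest were Ctsk, F7, Slc39a2, Akr1b8, Flrt2, Rpgrip1, Met, Pkp2, Nqo1 and Trem2. The protease gene Ctsk was 23.6-fold and 22.4-fold lower, the receptor kinase gene Met 23.8-fold and 15.5-fold, the quinone reductase gene Nqo1 13.1-fold and 17.3-fold, and Trem2, a lipid-sensing myeloid receptor gene, 15.02-fold and 12.5-fold. Among genes below the floor on both arrays of 1 genotype, C1qa was at least 185-fold and 92.7-fold higher in LXR-DKO, followed by Ngp, Retnla, Stfa2l1 and Dpp4. Galnt9 was at least 30.2-fold lower with LPS and was followed by Fkbp9, Cyp4a12a, Ednrb and Fkbp11. Sex-linked genes differed as well. Xist, which is expressed from the inactive X chromosome of female cells, had signals of 30.8 and 22.7 on the WT arrays and of 2750.0 and 2090.4 on the LXR-DKO arrays. The Y-linked gene Eif2s3y had signals of 736.6 and 721.0 against 279.6 and 384.3, and Uty of 300.9 and 291.1 against 69.7 and 128.6. Kdm5d, also Y-linked, had 126.2 and 98.1 against 56.1 and 93.2, and so hardly differed with LPS.

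Counting all genes, 1487 were at least 2-fold higher and 1088 lower in LXR-DKO among 11728 measured without LPS, and 2141 were higher and 1053 lower among 12014 with LPS. Of 11264 genes measured in both conditions, 1163 were higher and 693 lower in both, where independent lists would share 272 and 99.5, and the log2 ratios of the 9623 genes at or above the floor on all arrays correlated with r = 0.83. Any difference in mice, cells or array processing between the genotypes that was present in both conditions would add to this overlap. It is therefore not a replication of a genotype effect. The split depended on the scaling. Genes higher in LXR-DKO were 57.7% of those counted without LPS and 67.0% with LPS in the values as deposited, 44.1% and 47.1% at the same 75th percentile, 49.6% and 55.4% after quantile normalization, and 72.8% and 83.3% at the same level of hybridisation controls. The median log2 ratio of all genes with LPS was 0.15 as deposited, -0.11 at the same 75th percentile and 0.43 at the same level of hybridisation controls.

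**Figure D2:**
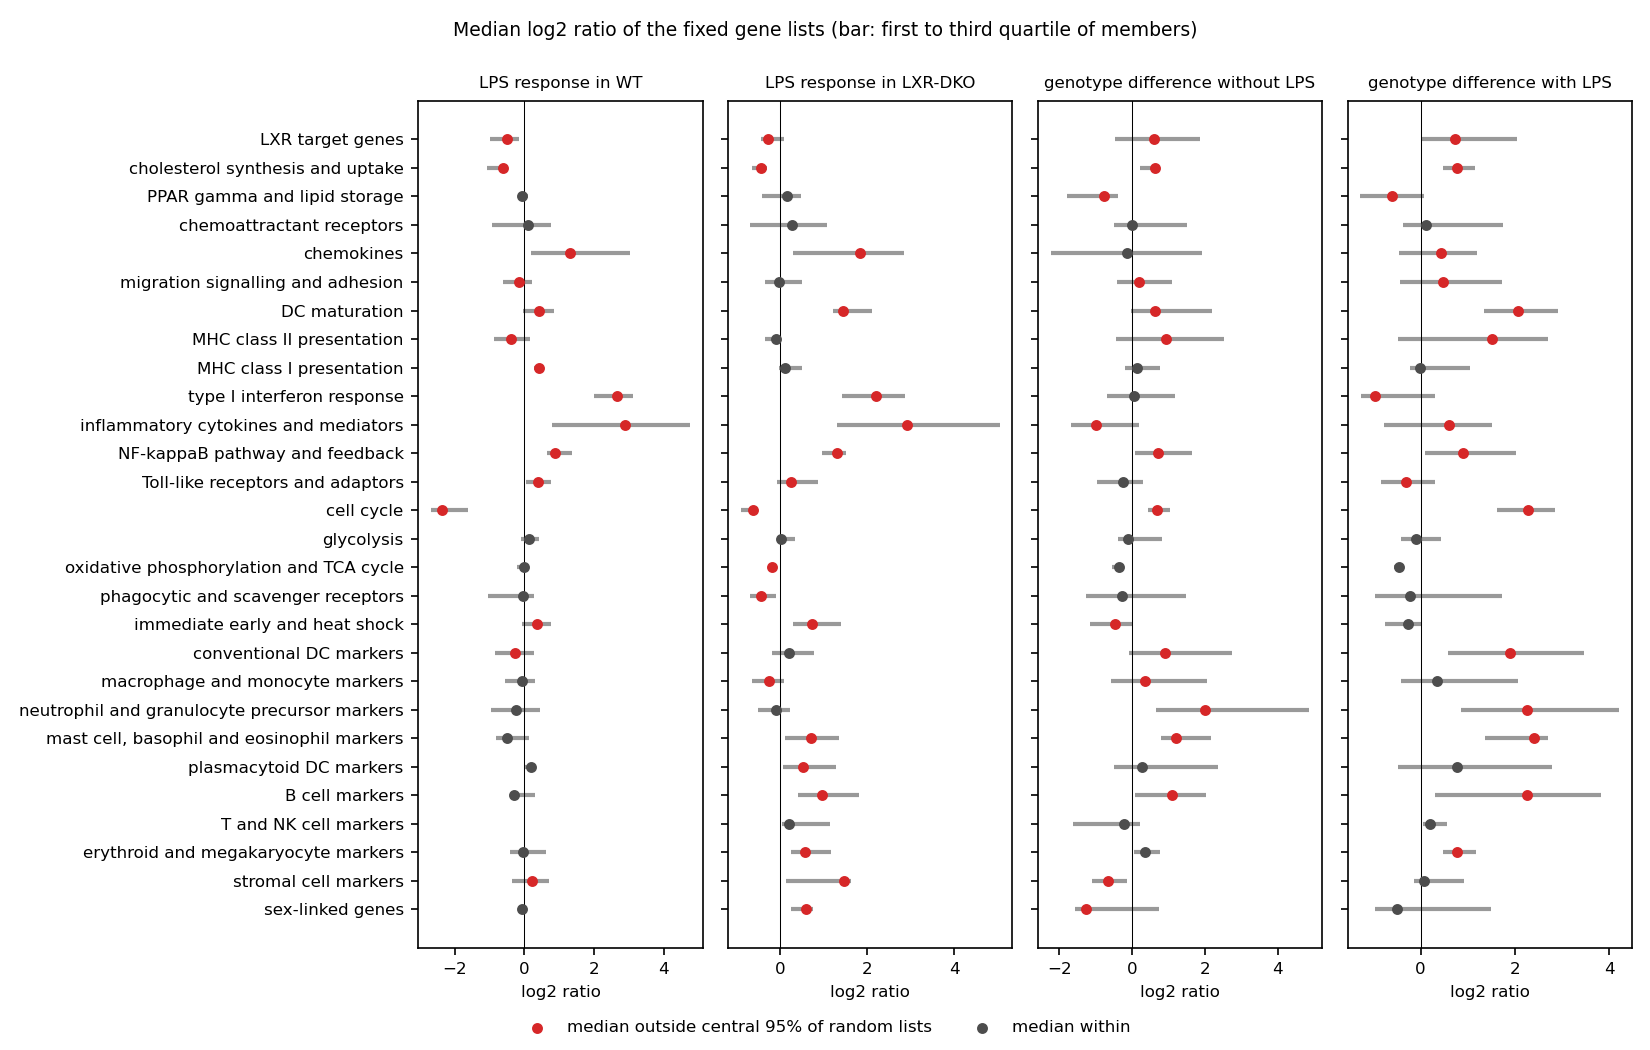
Each row is 1 of the 28 fixed gene lists and each panel 1 of 4 comparisons, with the log2 ratio (LPS over control, or LXR-DKO over WT) on the horizontal axis. Points are medians over the measured members and bars run from the first to the third quartile, and red points lie outside the central 95% of random lists. The cell cycle median is -2.36 for LPS in WT and -0.62 in LXR-DKO, and the DC maturation median 0.43 and 1.46.

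The third comparison asked whether the response to LPS itself differed between the genotypes. DC maturation genes were higher with LPS by more in LXR-DKO than in WT, and cell cycle genes were lower by less. In WT, 4 of 20 measured DC maturation genes were at least 2-fold higher with LPS and 2 lower, with a median log2 ratio of 0.43. In LXR-DKO, 18 of 21 were higher and 0 lower, with a median of 1.46. The median difference of the log2 responses, LXR-DKO minus WT, was 1.07 and lay above all random lists. Cd200, an inhibitory surface ligand gene, differed by 3.61, Ccr7 by 2.26 and Tnfsf4, the OX40 ligand gene, by 2.22. For Cd200, the log2 ratio of LXR-DKO over WT was -2.78 without LPS and 0.83 with LPS, so the genotypes differed mainly without LPS. Cell cycle genes had a median difference of 1.55, but of 0.53 with the floor at the 75th percentile, with Ccnb2 at 2.47 and Cdc20 at 2.36. Inflammatory cytokines and mediators had a median difference of 1.00, or 0.53 at the lowest of the alternatives. Among them, Il12b, the shared subunit of interleukins 12 and 23, had signals of 21.7 and 61.0 in WT and of 34.9 and 1016.2 in LXR-DKO. The type I interferon response list went the opposite way with a median difference of -0.56, and Rtp4 differed by -2.47. B cell markers had a median difference of 1.45 and stromal cell markers of 0.73, but of 0.13 with the floor at the 75th percentile. Chemokines had a median difference of 0.23, at the percentile of 97.0, and members went both ways, with Ccl2 at 3.99, Ccl7 at 3.59 and Ccl3 at 3.35 against Ccl5 at -2.81. Ccl2 and Ccl5 differed between the genotypes mainly without LPS. Their log2 ratios of LXR-DKO over WT were -4.06 and 3.12 without LPS, but -0.07 and 0.31 with LPS.

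The 8 genes with the highest difference were Fabp4, Itm2a, Plac8, Ccl2, Fstl1, Igfbp4, Tspoap1 and Cd200. Fabp4 was lower with LPS in WT at -3.001 and higher in LXR-DKO at 1.65, a difference of 4.65. Its signals were 707.9 and 88.4 in WT without and with LPS, and 46.9 and 147.2 in LXR-DKO, so the genotypes differed mainly without LPS. Itm2a had signals of 37.3 and 82.8 in WT and of 46.5 and 2213.6 in LXR-DKO. The 8 lowest were Slamf6, Sh3tc1, Ccl5, Abca1, Slfn5, Palld, Rtp4 and Taf7. Slamf6, a receptor of the SLAM family, was 17.2-fold higher with LPS in WT and 1.69-fold in LXR-DKO, and Abca1 17.8-fold and 2.82-fold. Abca1 was already 9.18-fold higher in LXR-DKO than in WT without LPS, against 1.45-fold with LPS. In all, the difference of the responses was 2-fold or more for 1207 of 12478 genes, 949 of them higher and 258 lower in LXR-DKO, against a spread between probe sets of 0.43. A difference of responses draws on all 4 arrays, so any fault of 1 array enters it in full.

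**Figure D3:**
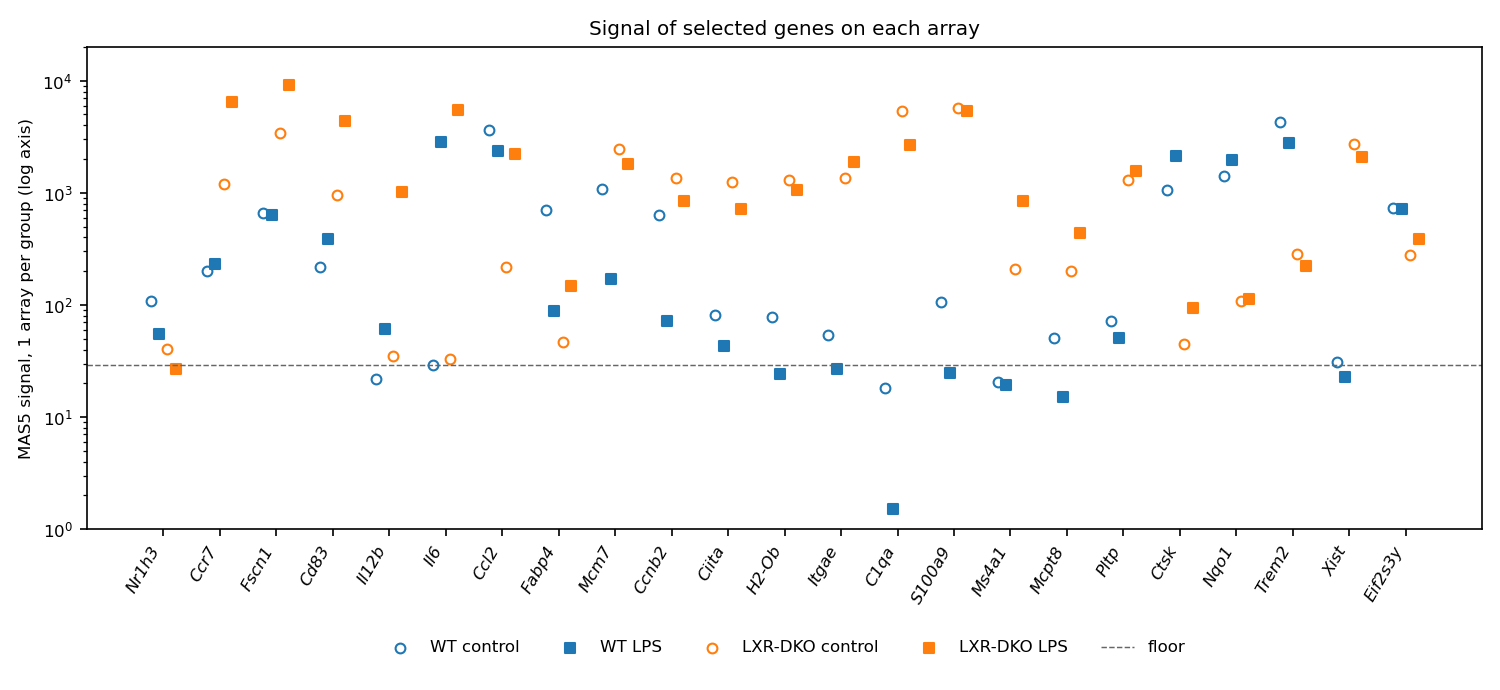
Points are the MAS5 signals of selected genes on each of the 4 arrays, on a log axis, with open symbols for control and filled symbols for LPS cultures. The dashed line is the floor of 28.9. Ccr7 lies at 201.3 and 229.8 in WT and at 1189.3 and 6482.5 in LXR-DKO, and Ctsk at 1050.2 and 2118.3 in WT and at 44.5 and 94.5 in LXR-DKO.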

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

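Except for the tests of array scaling, the tests in this part were chosen after the results were seen, as was the scaling to hybridisation controls among the 4 scalings. Some genes responded to LPS at least 2-fold in opposite directions in the genotypes. There were 17, and the difference was not tested because each group has 1 array. Among the genes named above, the difference of the log2 responses, LXR-DKO minus WT, was 4.65 for Fabp4, 4.11 for Plac8, 3.68 for Igfbp4, 3.64 for Tspoap1 and -2.36 for Taf7. Signals outside the main measurement differed too. The control probe set for the B1 repeat, a short interspersed element, was 5.32-fold higher in WT control than in LXR-DKO control. With LPS it was 4.24-fold higher in WT. Control transcripts with a poly-A tail, added to the RNA before labelling, were 1.93-fold higher in WT control than in LXR-DKO control. The 5' probe set for 18S ribosomal RNA was 3.97-fold higher in WT LPS than in WT control, with signals of 510.6 and 2025.2 in WT control and LPS against 77.4 and 69.5 in LXR-DKO. Of the probe sets without a listed gene, 426 were at least 2-fold apart between the genotypes without LPS.

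The first pattern is that more genes differed at least 2-fold between the genotypes, 2575 without LPS and 3194 with LPS, than with LPS, 884 in WT and 950 in LXR-DKO. Under the 4 other scalings the smaller genotype count stayed at least 2.65 times the larger LPS count. Scaling by a constant per array mainly moves genes between higher and lower, so this is a weak test and speaks only against the scalings tried. The excess depended on the threshold, however: beyond 3 SD of each comparison's own spread between probe sets, which was larger between genotypes, genes numbered 1510 without LPS and 1428 with LPS between genotypes against 1139 in WT and 601 in LXR-DKO with LPS, and the smaller genotype count was 1.25 times the larger LPS count instead of 2.71 times. Cells of other types may account for the genes that mark them: all 3 of the lists for B cells, for mast cells, basophils and eosinophils, and for neutrophils lay above the central 95% of random lists in LXR-DKO both without and with LPS, although with the floor at the 75th percentile those for B cells and for mast cells, basophils and eosinophils lay inside it without LPS. CD11c selection should remove most such cells, and their share is not known. Separate processing of the genotypes cannot be told apart from genotype, because each holds its own arrays, and the poly-A controls differed by -0.95 on the log2 scale without LPS and by -0.60 with LPS, though also by 0.43 between the LXR-DKO arrays. The loss of LXRs stays open as the biological explanation and was not tested apart from the mice used.

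The second pattern is the stronger LPS response of DC maturation genes in LXR-DKO. Under the 4 other scalings the lowest median difference was 0.96 and outside the central 95% of random lists each time. A constant per array shifts the random lists along with this list, so its place among them could hardly change. The median difference over all genes moved only between -0.01 and 0.16, so none of these scalings accounts for a difference of this size. A culture of WT cells that had matured before LPS might have had the list higher in WT, but without LPS the list's median was 0.63 in LXR-DKO over WT. This cannot exclude it, since conventional DC markers were also higher in LXR-DKO, by a median of 0.91. Inflammatory cytokines and mediators had a median of -1.003, or -0.24 without a floor, with 8 of 16 at least 2-fold lower in LXR-DKO and 3 higher. Cd200 had signals of 775.0 in WT control and 112.5 in LXR-DKO control. An activated WT control thus stays open. B cells in the LXR-DKO culture may add to the stronger response, since B cell markers differed in their response by a median of 1.45. Other cell markers also did, with medians of 0.44 for conventional DC markers and 0.55 for erythroid and megakaryocyte markers, against 0.005 for neutrophil markers. A part of B cells stays open because the share of such cells is not known and B cells also express Ccr7, Cd40 and Cd86. An effect of LXRs on the response remains among the open explanations.

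The third pattern is the sex-linked genes. A swap of a WT and an LXR-DKO array is argued against by Xist, whose lower LXR-DKO signal was 67.9 times the higher WT signal. Cells of female mice alone in LXR-DKO cannot be told apart from cells of both sexes: the median signal of 3 Y-linked genes on the LXR-DKO arrays was 110.9, above the floor, but their probe sets may also bind transcripts of X-linked relatives, which was not examined. Sex of the mice, which the labels do not give, is a biological difference between the genotypes that stays open for the genotype comparisons.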

How the results depend on the processing

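No paired analysis was possible because each group has 1 array. The cause of the shifts below was not tested beyond what each setting does by construction: a lower floor lets in more dim genes, and a higher floor fewer. With the floor at the 25th percentile, genes higher and lower were 833 and 1235 for LPS in WT, 1541 and 560 for LPS in LXR-DKO, and 2223 and 924 for the difference of the responses, and 1863 were lower in LXR-DKO without LPS. With the floor at the 75th percentile they were, in the same order, 188 and 150, 324 and 114, and 281 and 148, and further 744 and 611 between genotypes without LPS, and 947 and 685 with LPS, and the spread between probe sets for LPS in WT was 0.19. Without a floor, 457 genes were lower for the difference of the responses. Scaling to the same 75th percentile gave 1724 genes lower in LXR-DKO with LPS, and scaling to hybridisation controls, chosen after seeing the data, 622. All other counts, spreads, numbers of lists outside the random range and ratios of Nr1h3, 180 of 201 in all, stayed within 1.5 times their main value or within the spread between probe sets. Leaving out genes on X and Y, also chosen after seeing the data, gave 1461 and 1044 genes between genotypes without LPS. Among list medians outside the random range, 6 changed sign, 1 of them under 2 settings. Under scaling to the same 75th percentile, the migration signalling and adhesion list without LPS was at -0.015. With the floor at the 25th percentile, the difference of the responses was 0.018 for phagocytic and scavenger receptors and 0.0096 for macrophage and monocyte markers. With the floor at the 75th percentile, the LPS response in WT was 0.28 for conventional DC markers and -0.049 for stromal cell markers. Without a floor, the phagocytic and scavenger receptors differed by 0.035, and with hybridisation control scaling the Toll-like receptors and adaptors in LXR-DKO over WT with LPS were at 0.00012. Other list medians given in the text moved by 1.5-fold or more without a change of sign, and those that follow are examples. Between genotypes without LPS, the lowest alternative was 0.025 for macrophage and monocyte markers and 0.31 for NF-kappaB pathway genes. With LPS it was 0.034 for chemokines, 0.18 for migration signalling and adhesion and 0.35 for inflammatory cytokines and mediators. Immediate early and heat shock genes without LPS rose to -0.25. With the floor at the 75th percentile, LPS medians were -1.34 for the cell cycle in WT and, in LXR-DKO, 1.35 for the interferon response, 1.81 for inflammatory cytokines and mediators and 0.08 for stromal markers. Between genotypes that floor gave 0.23 for B cell markers without LPS, and with LPS 1.16 for the cell cycle, 1.25 for mast cell, basophil and eosinophil markers and 1.35 for DC maturation, and the difference of the responses was 0.53 for the cell cycle and 0.13 for stromal markers. Without a floor, LPS medians in WT were 0.32 for chemokines and 1.38 for inflammatory cytokines and mediators, whose genotype difference without LPS was -0.24. B cell markers with LPS stood at 1.13 after quantile normalization, and with only probe sets without a suffix the neutrophil markers without LPS stood at 1.18 and the mast cell, basophil and eosinophil markers at 1.997, and the plasmacytoid DC markers at 0.89 without LPS and 1.44 with LPS. Of the genes named, Xaf1 alone changed sign while at least 2-fold apart, because another of its probe sets became the brightest, with genotype ratios of -2.25 without LPS and -5.55 with LPS under 75th percentile scaling and of -2.12 and -5.36 under median ratio scaling. Signals near the floor limit the ratios of dim genes.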

Other observations

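The NRF2 target list and the lysosomal list were chosen after the data were seen and hold genes already known to be lower, such as Nqo1, Akr1b8 and Ctsk, so their values describe that observation and do not test it. Genes of the antioxidant regulator NRF2 were lower in LXR-DKO in both conditions. Of these, 12 of 20 measured were at least 2-fold lower without LPS and 13 of 21 with LPS, with 0 higher and median log2 ratios of -1.55 and -1.61. The haem oxygenase gene Hmox1 had signals of 2952.9 and 6094.8 in WT and of 319.3 and 775.0 in LXR-DKO, and the cystine transporter gene Slc7a11 had log2 ratios of -3.99 and -2.67. Osgin1 went the other way at 0.79 and 0.94. Lysosomal genes had medians of -0.74 and -0.90, with 8 of 29 and 10 of 29 at least 2-fold lower and 0 higher. The proton pump subunit gene Atp6v0d2 stood at -3.02 and -3.23 and the galactosidase gene Gla at -3.49 and -3.27, and the cathepsin gene Ctsc lay above 0 at 0.14 and 0.16.

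Of the genotype medians in this paragraph, those of NF-kappaB pathway genes in both conditions, of Toll-like receptors and of erythroid and megakaryocyte markers with LPS, and of stromal and sex-linked genes without LPS lay outside the central 95% of random lists, and the others lay inside. For Toll-like receptors and for erythroid and megakaryocyte markers this held under only 4 and 5 of the 9 alternatives. Toll-like receptors and adaptors had a median of -0.27 without LPS and -0.32 with LPS, the latter just above 0 under hybridisation control scaling, and the RNA sensor genes Tlr7 and Tlr13 stood at -2.50 and -1.54 without LPS. Genes of oxidative phosphorylation and the TCA cycle had medians of -0.36 and -0.45, with Ndufa4 at -1.74 and -1.83 against Fh1 at 0.82 and 1.19. Glycolysis genes had medians of -0.12 and -0.10, both above 0 under hybridisation control scaling and with only probe sets without a suffix and the first also with the median over probe sets, and went both ways, with the glucose transporter genes Slc2a3 at 2.66 and Slc2a1 at -1.31 without LPS. Phagocytic and scavenger receptors had medians of -0.29 and -0.22, the latter above 0 under hybridisation control scaling, with 7 of 22 at least 2-fold higher and 7 lower without LPS, led on the lower side by Marco at -3.09. NF-kappaB pathway genes had medians of 0.72 and 0.89, and class I presentation genes of 0.13 and -0.01, the first below 0 under 75th percentile scaling and the second above 0 under quantile normalization, hybridisation control scaling and both probe set alternatives, with Tap1 at 2.06 and 2.03. Plasmacytoid DC markers had medians of 0.27 and 0.78, but of 0.89 and 1.44 with only probe sets without a suffix, T and NK cell markers of -0.23, above 0 under hybridisation control scaling, with the floor at the 25th percentile and without a floor, and 0.20, and erythroid and megakaryocyte markers of 0.36 and 0.77. Stromal cell markers had medians of -0.66 and 0.07, the latter below 0 under 75th percentile scaling, quantile normalization, median ratio scaling and with the floor at the 75th percentile, and with LPS they were higher in LXR-DKO cultures by a median of 1.48, but of 0.08 with the floor at the 75th percentile, with the proteoglycan gene Dcn at 3.02 there and 2.71 in WT. The sex-linked list had a median of -1.28 without LPS and -0.49 with LPS.

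DNA of another strain around the targeted genes was weighed as a hypothesis, with the test fixed before its result was seen. Of the 200 genes nearest to Nr1h3 and Nr1h2, 50 on each side, 17.5% differed at least 2-fold the same way in both conditions, against 16.5% of all 11264 genes measured, and this lay within the central 95% of 10000 random pairs of such blocks. Of 100 neighbours each, 11 differed so around Nr1h3 and 24 around Nr1h2. The shares are too close to decide whether such DNA contributed, and the labels give the same strain for all samples.

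A further hypothesis, with its test also fixed before its result was seen, is that transcript or sequence variants between the genotypes may turn probe sets of 1 gene in opposite directions, as for Xaf1. Among genes with a probe set at least 2-fold apart, 0.67% had probe sets at least 2-fold in opposite directions for the genotype difference without LPS, 13 of 1938 genes. For the LPS responses it was 0 of 616 in WT and 4 of 1023, or 0.39%, in LXR-DKO, and with LPS the genotype difference gave 38 of 2435, or 1.56%. The excess is consistent with such variants, but rests on few genes, and a larger spread between probe sets in the genotype comparisons was seen as well.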
